A study of Rattus norvegicus with 8 samples.

How the data were processed

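Gene expression was measured with an Affymetrix rat array in RNA from the femur growth plate of Rattus norvegicus, the cartilage layer through which long bones lengthen. The labels name 4 zones of the plate (perichondral, reserve, proliferative and hypertrophic) and give each zone 1 array from rats aged 42 days and 1 array from rats aged 46 days. Per the labels, each array received RNA pooled from 3 rats, extracted on RNeasy columns, amplified with the Ovation method and labelled with biotin. How the zones were separated is not given in the sources used here, nor whether pools of different zones came from the same rats. The design text counts the ages as replicates, so every zone has n = 2 arrays. The p-values of single probe sets measure the spread between pools that also differ in age. Those of gene lists also rest on how far the genes of a list are taken to vary independently.

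The deposited values are linear array intensities for 31099 probe sets. The submitters' processing notes name MAS5, GCOS and RMA, without versions and without the role of each. The mean deposited intensity after trimming a share of 0.02 lay between 500.08 and 500.16 in all 8 arrays, so the arrays share one scale. The median deposited intensity ran from 226.6 (reserve, 42 days) to 348.9 (proliferative, 46 days). Detection calls were not used here, and the number of arrays limits the precision.

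From these values, 57 control probe sets were left out and 31042 were analysed as log2(intensity + 16). Array medians on that scale ran from 7.92 to 8.51. A gap of more than 0.1 called for quantile normalization under the rule set beforehand, so values were quantile normalized between arrays, with limma 3.58.1 in R 4.3.3. Differences and folds are on this log2(intensity + 16) scale, which understates the difference of dim genes, and all changes are relative to the normalized median of 8.25. As a yardstick for background, 32 genes typical of organs other than bone were followed, and the 0.95 quantile of their values was 9.18, called the other-organ level here.

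Gene names came from the platform annotation, with 20758 probe set symbols updated through gene identifiers. Of the probe sets analysed, 20826 had 1 gene symbol, 436 had several and 9780 had none, and no gene was named from a probe set with several. No genome build is named for these values, so positions are not given. Gene lists used 1 probe set per gene, the one with the highest mean, which gave 14217 genes.

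One linear model with a mean per zone was fitted to all 8 arrays with limma (empirical Bayes with a variance trend, 4 residual and 12.58 prior degrees of freedom). The 6 pairs of zones were tested with Benjamini-Hochberg adjustment over all probe sets, and the threshold was an adjusted p below 0.05. A probe set counted as enriched in a zone when it was higher there than in each of the other 3 zones at that threshold. Age was tested with zone as a covariate, which leaves 3 residual degrees of freedom. For 29 gene lists, limma's camera was run with a preset correlation of 0.01 between genes and adjusted over 174 tests, each list in each of the 6 comparisons. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, served as alternatives. For the lists called, the estimated correlation ran from 0.027 (endothelial) to 0.424 (cartilage matrix), above the preset value. Every list call said to hold or be lost with an array left out used the preset value, so holding there does not test it. The lists cover chondrocyte stages, other cell types that a dissected zone could hold, cell division, signalling, metabolism and stress, and some genes stand in several of them.

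Genes were named by a rule. For perichondral against reserve these were the 10 genes with the largest difference in each direction, and for each other comparison 5. Each had to be past the threshold, with 1 gene symbol, both arrays of one zone above both of the other, and a mean in the higher zone above the median of all probe sets. List members were named by the size of their difference, up to 4 per list. A further 16 growth plate genes were to be given in any case, of which 11 had a probe set with a single gene name. Genes named outside this rule are said to be so. The comparisons, tests, lists and rule, and all alternatives not called added, were fixed before the data were examined.

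The labels give the same ages to every zone, so the fit with age as a replicate block was treated as the paired fit. As a check, the difference between 46 and 42 days was correlated between zones across all probe sets, with r from 0.0225 to 0.0806, and from 0.0581 to 0.31 across the brightest share of 0.2. These correlations are across genes, which are not independent replicates. Counts from the blocked fit stand beside the results that they move.

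The test was checked on simulated data drawn from the means and spread of 31042 probe sets, with 5 simulations per size of change. In each, 200 probe sets with a mean above the median were changed between perichondral and reserve. Among these brighter probe sets the test recovered 0% of changes of 1 on the log2 scale and 1.2% of changes of 2. It recovered 87.3% of changes of 4 and 99.8% of changes of 6. Recovery of changes in dimmer probe sets was not simulated. Of the probe sets called, 14.3%, 5.31% and 7.25% were false at changes of 2, 4 and 6, where the threshold aims at 5%. The share at 2 rests on few calls, as only 1.2% of those changes were recovered. The sampling error of these shares was not estimated. Camera recovered a shift of 2 in a list of 20 genes in 100% of 100 simulations on 14217 genes, and called 4% of lists without a shift. Simulated genes varied independently, so this does not test the preset correlation. Alternatives covered the age block, normalization, filters on dim probe sets, the variance model, array weights, the arrays in the fit, thresholds, pseudocounts of 1 and 64, the probe set used per gene, the list tests and leaving out each array.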

Results

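Gene expression was profiled in 4 zones of the rat femur growth plate with 8 arrays, 1 per zone at 42 days and 1 per zone at 46 days of age. The series title sets the perichondral zone, at the rim of the plate, beside the reserve zone, which holds resting chondrocytes. Col2a1, the main collagen of cartilage, averaged 17.69 ± 0.16 (SD, n = 2) in perichondral, 17.49 ± 0.13 in reserve, 17.31 ± 0.14 in proliferative and 16.50 ± 0.90 in hypertrophic arrays on the log2 scale. Across the brightest share of 0.2 of probe sets, arrays of one zone correlated with r from 0.531 to 0.769 and arrays of different zones with r from 0.357 to 0.78. The 46-day proliferative and hypertrophic arrays correlated at 0.735, above the 0.615 and 0.531 of each with the other array of its own zone. These correlations are across genes, which are not independent replicates.

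Marrow, blood and bone-resorbing cell genes were lower in perichondral than in reserve arrays. The leukocyte and marrow list had a mean log2 difference of -2.27 (SE 0.43 over 22 genes, 20 of them lower, adjusted p = 1.22e-09 with limma's camera). The erythroid list had a mean of -2.05 (SE 0.55, 9 of 10 genes, adjusted p = 2.46e-06) and the osteoclast list -2.03 (SE 0.54, 10 of 10 genes, adjusted p = 6.28e-06). Hypertrophic chondrocyte genes (-1.10, SE 0.39, 17 of 20 genes, adjusted p = 0.00108), endothelial genes (-0.996, SE 0.211, 11 of 13 genes, adjusted p = 0.0106) and matrix proteases with their inhibitors (-0.67, SE 0.31, 16 of 26 genes, adjusted p = 0.0364) were lower as well. None of these 6 calls held with an estimated correlation (adjusted p = 0.651 for each). The medians of the endothelial and leukocyte lists lay below the other-organ level in both zones at both ages. The 3' to 5' signal ratio of the Gapdh control, a sign of RNA quality, also differed between these zones, at 4.47 and 3.78 in perichondral against 8.15 and 3.96 in reserve arrays at 42 and 46 days.

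With the preset correlation of 0.01, the leukocyte, erythroid and osteoclast calls between these zones held with each array left out. The estimated correlations of these lists were higher, at 0.146, 0.272 and 0.131. Their differences then ran from -2.585 to -1.996, from -2.307 to -1.761 and from -2.628 to -1.316, in the same order. The hypertrophic chondrocyte call was lost without the 42-day reserve array (-0.73, adjusted p = 0.102). The endothelial call was lost without the 46-day perichondral array (adjusted p = 0.0589) or the 46-day reserve array (adjusted p = 0.131). The protease call was lost without the 42-day hypertrophic array (-0.667), the 46-day perichondral array (-0.487) or the 42-day reserve array (-0.282).

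Adjusted over the list alone, 5 leukocyte and marrow genes were lower in perichondral arrays, against 0 over all probe sets. They included S100a8, a neutrophil protein (-6.74, SE 1.555), Cd68, a macrophage protein (-5.98, SE 1.40), and S100a9, the partner of S100a8 (-4.69, SE 0.74). Adjusted over the list alone, 4 erythroid genes were lower, among them Ahsp, a chaperone of alpha globin (-4.635, SE 1.29), and Hemgn, a nuclear protein of blood-forming cells (-4.55, SE 0.89). Of the osteoclast genes 3 were lower, namely the gelatinase Mmp9 (-5.50, SE 0.93), the carbonic anhydrase Car2 (-3.41, SE 1.09) and the integrin Itgb3 (-3.27, SE 0.97). In the hypertrophic chondrocyte list that adjustment left 3 genes lower, Mmp9, the collagenase Mmp13 (-3.81, SE 0.665) and Dmp1 (-3.872, SE 0.985), and 1 higher, Col10a1. Of the genes named as lower here only Mmp13 was above the other-organ level in perichondral arrays, so the other sizes rest on dim values. Mmp9 stands in the hypertrophic, osteoclast and protease lists. Without the 6 measured members that the hypertrophic list shares with the bone and osteoclast lists, an alternative added after seeing the data, its difference was -0.72 (adjusted p = 0.0916).

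Single probe sets between perichondral and reserve arrays gave 0 past the threshold with limma, 1164 had an unadjusted p under 0.05 where chance gives 1552, and so the rule named no gene. With age as a replicate block 3 passed, all lower in perichondral arrays, and they are named here after their values were seen. S100a9 was at 8.76 ± 1.23 (SD, n = 2) in perichondral and 13.45 ± 0.15 in reserve arrays (adjusted p = 0.0233 with the block, 0.251 without). Mmp13 was at 10.93 ± 1.63 and 14.74 ± 0.02 (adjusted p = 0.0233 with the block, 0.276 without). Mmp9 was at 7.20 ± 2.60 and 12.70 ± 0.85 (adjusted p = 0.0379 with the block, 0.276 without). A fit to the 4 arrays of these zones alone called 9 probe sets, all lower in perichondral arrays. With each array left out, the Mmp9 difference ran from -7.28, without the 42-day perichondral array, to -3.67.

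The cartilage matrix, resting chondrocyte and fibrous lists were not called between perichondral and reserve arrays. The cartilage matrix list had a mean difference of -0.16 and a median of 0.11 over 24 genes (adjusted p = 0.879), the resting chondrocyte list a mean of -0.175 (adjusted p = 0.943), and the fibrous perichondrium and periosteum list 0.19 (adjusted p = 0.382). Col10a1, the collagen of hypertrophic cartilage, was at 13.72 ± 0.08 (SD, n = 2) in perichondral and 11.33 ± 0.63 in reserve arrays, a difference of 2.39 (SE 0.715) that missed the threshold over all probe sets (adjusted p = 1). The difference was 0.20 (SE 1.25) for Col2a1, -0.66 (SE 0.70) for the proteoglycan Acan and -0.60 (SE 0.58) for the growth factor receptor Fgfr3. It was -0.04 (SE 0.70) for the parathyroid hormone receptor Pth1r and -0.09 (SE 1.16) for the secreted signal Ihh, which was below the other-organ level in both zones at 5.585 and 5.67. It was -1.51 (SE 1.10) for Col1a1, 1.13 (SE 0.74) for Col3a1, -1.02 (SE 0.62) for the proliferation marker Mki67 and -0.77 (SE 0.73) for Spp1, and each of these 9 genes had an adjusted p of 1. The signs for Acan, Pth1r and Ihh turned with the arrays used: without the 42-day reserve array Acan was at 0.37 and Pth1r at 0.36, and without the 42-day perichondral array Pth1r was at 0.34 and Ihh at 0.32. Other genes kept their signs but moved in size with each array left out. Col1a1 ran from -2.688 to -0.301, Col3a1 from 0.352 to 1.869 and Fgfr3 from -1.029 to -0.164. Mki67 ran from -1.579 to -0.459, Spp1 from -1.068 to -0.473 and Col2a1 from 0.09 to 0.327.

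**Figure D1:**
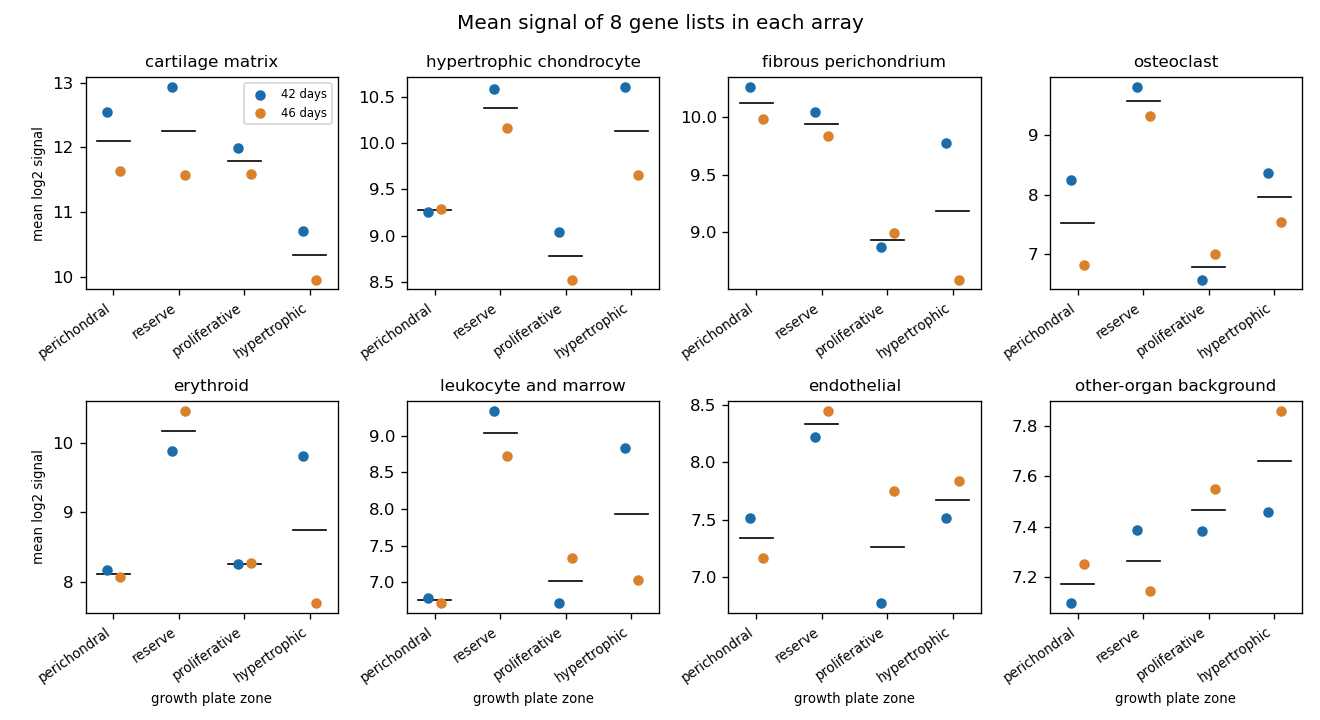
Mean log2 signal (vertical axis) of 8 gene lists in each array, by zone (horizontal axis), with 42-day arrays in blue, 46-day arrays in orange and a black line at the mean of both. Leukocyte and marrow genes averaged 9.34 and 8.72 in the reserve arrays against 6.79 and 6.725 in the perichondral arrays.

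Fibrous connective tissue genes were higher in perichondral than in proliferative arrays. The fibrous perichondrium and periosteum list was higher by 1.19 (SE 0.26, 26 of 34 genes, adjusted p = 4.7e-06) and the tendon and ligament list by 1.502 (SE 0.739, 6 of 7 genes, adjusted p = 0.0236). Adjusted over the list alone, 8 fibrous genes were higher, against 0 over all probe sets, led by Col1a1, a collagen of bone and fibrous tissue (4.54, SE 1.10), the matrix protein Postn (3.44, SE 1.12), Col1a2 (3.28, SE 0.98) and the proteoglycan Ogn (3.13, SE 0.74). Postn was below the other-organ level in proliferative arrays. Col1a1 stands in the fibrous, tendon and bone lists. Both calls were lost with an estimated correlation (adjusted p = 0.651). The Gapdh 3' to 5' ratio also parted these zones, at 4.47 and 3.78 in perichondral against 7.10 and 5.39 in proliferative arrays at 42 and 46 days. Camera was also run on these lists with the log2 of this ratio as a covariate, but that outcome was not kept. The bearing of the ratio on these calls is therefore not known. The fibrous call held with each array left out, while the tendon call was lost without the 42-day perichondral array (0.80, adjusted p = 0.385), the 42-day proliferative array (adjusted p = 0.0974) or the 46-day proliferative array (adjusted p = 0.122).

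Between perichondral and proliferative arrays 0 probe sets passed with limma, with 1551 at an unadjusted p under 0.05, and 13 passed with the age block, all higher in perichondral arrays. Leaving out an array gave 4 without the 42-day hypertrophic, 5 without the 46-day hypertrophic and 2 without the 42-day proliferative array.

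Perichondral arrays stood above hypertrophic arrays in cartilage matrix genes and in 5 genes named by the rule. Nnt, a mitochondrial transhydrogenase, was at 11.49 ± 0.32 (SD, n = 2) against 5.28 ± 0.10, a 74-fold difference (adjusted p = 0.00379). Ucma, a secreted cartilage protein, was at 15.39 ± 0.57 against 9.27 ± 0.16, 69.6-fold (adjusted p = 0.00379). Omd, a proteoglycan of bone, was higher 72.5-fold (adjusted p = 0.0218), the ubiquitin ligase Pdzrn3 61-fold (adjusted p = 0.0102) and Arxes1 33.2-fold (adjusted p = 0.0218). Of these only Ucma was above the other-organ level in hypertrophic arrays. The cartilage matrix list was higher by 1.76 (SE 0.33, 23 of 24 genes, adjusted p = 2.8e-09), with 7 genes higher when adjusted over the list alone and 1 over all probe sets, among them the collagen-binding proteoglycan Fmod (4.94) and Chad (4.61), both below the other-organ level in hypertrophic arrays. This call was lost with an estimated correlation (adjusted p = 0.651).

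The fibrous list (0.94, SE 0.235, 27 of 34 genes, adjusted p = 0.00108), the resting chondrocyte list (1.03, SE 0.405, 12 of 17 genes, adjusted p = 0.0174) and the Wnt signalling list (0.765, SE 0.27, 21 of 32 genes, adjusted p = 0.0227) were also higher in perichondral than in hypertrophic arrays. In these lists 2, 2 and 4 genes were higher when adjusted over the list alone, against 1, 0 and 0, among them Ogn (4.50), Tgfbi (3.13) and the Wnt inhibitor Wif1 (4.08), all below the other-organ level in hypertrophic arrays and Wif1 in perichondral arrays too. Leukocyte and marrow genes (-1.17, SE 0.22, 19 of 22 genes, adjusted p = 0.00108) and hypertrophic chondrocyte genes (-0.855, SE 0.379, 15 of 20 genes, adjusted p = 0.00938) were lower, with 0 and 3 genes lower when adjusted over the list alone, against 0 in both, the latter being Mmp9 (-4.94), Mmp13 (-3.48) and Col10a1 (-2.38). Mmp9 was below the other-organ level in perichondral arrays. These 5 calls were lost too with an estimated correlation (adjusted p = 0.651).

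Only the cartilage matrix call between these zones held with each array left out. Without the 42-day hypertrophic array the leukocyte difference was -0.18 (adjusted p = 0.6), the hypertrophic -0.30 (adjusted p = 0.476), the resting 1.08 (adjusted p = 0.111) and the Wnt 0.68 (adjusted p = 0.259). Without the 46-day hypertrophic array the fibrous difference was 0.50 (adjusted p = 0.166). The resting call was also lost without the 42-day perichondral (adjusted p = 0.385) or the 42-day proliferative array (adjusted p = 0.082). The Wnt call was lost without either perichondral array (adjusted p = 0.0806 and 0.206) or the 42-day proliferative array (adjusted p = 0.124).

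In all, 9 probe sets were higher and 0 lower in perichondral than in hypertrophic arrays with limma, and 52 and 3 with the age block, which held all 9. Without the 42-day perichondral array all 5 named genes lost the call (adjusted p from 0.229 to 0.999), as they did without the 46-day one (from 0.0999 to 0.36). Omd (adjusted p = 0.132), Pdzrn3 and Arxes1 (0.0768 for both) lost it without the 46-day hypertrophic array, and Arxes1 without the 42-day reserve array (0.0647). The count was 0 without either perichondral array, 5 without the 42-day reserve array and 50 without the 42-day hypertrophic array. Median-centred arrays gave 1, and Omd (adjusted p = 0.102), Ucma, Pdzrn3 and Arxes1 (0.0578 for each) lost the call there.

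Reserve arrays stood above proliferative arrays in 5 genes named by the rule. S100a9 was at 13.45 ± 0.15 (SD, n = 2) against 5.90 ± 0.65, a 187-fold difference (adjusted p = 0.000438). Mmp13 was at 14.74 ± 0.02 against 8.61 ± 0.06, 70.2-fold (adjusted p = 0.000948). Mmp9 was higher 138-fold (adjusted p = 0.00655), Lats2, a kinase of the Hippo pathway, 25.7-fold (adjusted p = 0.0334) and the metalloreductase Steap4 15.8-fold (adjusted p = 0.0162). All 5 were below the other-organ level in proliferative arrays.

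All 9 lists called in this comparison were higher in reserve arrays. Their mean differences were 2.77 for osteoclast (9 of 10 genes, adjusted p = 2.36e-06), 2.005 for leukocyte and marrow (17 of 22, adjusted p = 0.00033), 1.91 for erythroid (8 of 10, adjusted p = 0.00108) and 1.59 for hypertrophic chondrocyte genes (12 of 20, adjusted p = 0.0017). Matrix proteases were higher by 1.18 (20 of 26, adjusted p = 0.00184), osteoblast and bone genes by 1.81 (10 of 13, adjusted p = 0.00402), tendon and ligament genes by 2.14 (7 of 7, adjusted p = 0.0042), fibrous genes by 1.005 (24 of 34, adjusted p = 0.00598) and endothelial genes by 1.08 (9 of 13, adjusted p = 0.0445). Among osteoclast genes 6 were higher when adjusted over the list alone, against 1 over all probe sets, among them Itgb3 (4.52) and the collagen-degrading protease Ctsk (3.815). Leukocyte genes higher in this way were 7, against 1, led by S100a8 (8.845). The same adjustment gave 3 bone genes, against 0, namely Ibsp, a sialoprotein of mineralised matrix (6.19), Col1a1 (6.05) and Dmp1 (4.42), and 1 endothelial gene, against 0, the receptor Kdr (3.75). Of these members only Col1a1 was above the other-organ level in proliferative arrays. No call held with an estimated correlation (adjusted p = 0.651 for each). The median difference of the leukocyte and marrow list was 2.453 at 42 days and 0.011 at 46 days.

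The osteoclast, erythroid and hypertrophic chondrocyte calls between reserve and proliferative arrays held with each array left out, though the last had an adjusted p of 0.15 without the shared members. Without the 42-day proliferative array the fibrous (adjusted p = 0.082), bone (adjusted p = 0.0974), leukocyte (adjusted p = 0.0718) and endothelial (0.59, adjusted p = 0.489) calls were lost. Without the 42-day reserve array the tendon (adjusted p = 0.0652) and protease calls (adjusted p = 0.0734) were lost. The endothelial call was also lost with the age block (adjusted p = 0.0585), without either hypertrophic array (adjusted p = 0.0565 and 0.0532), without the 46-day reserve array (adjusted p = 0.189), as deposited (adjusted p = 0.0738) and median-centred (adjusted p = 0.0758).

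With limma, 7 probe sets were higher and 0 lower in reserve than in proliferative arrays, and 60 and 0 with the age block, which held all 7. Without the 42-day reserve array S100a9 and Mmp13 (adjusted p = 0.0865 for both), Mmp9 and Steap4 (0.434) and Lats2 (0.785) lost the call. Mmp13 also lost it without the 46-day proliferative array (0.0694), and Mmp9 without the 42-day proliferative (0.0691), the 46-day proliferative (0.0694) or the 46-day reserve array (0.0777). Lats2 also lost it without either perichondral (0.167 and 0.172), the 46-day proliferative (0.19) or the 46-day reserve array (0.183), and Steap4 without the 42-day perichondral (0.0531), either proliferative (0.0691 and 0.123) or the 46-day reserve array (0.132). The count was 0 without the 42-day reserve array, 1 without the 46-day proliferative array, 4 without the 42-day perichondral array, 35 without the 42-day hypertrophic array and 45 without the 46-day hypertrophic array.

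Reserve arrays were lower in Col10a1 than hypertrophic arrays and higher in cartilage matrix genes. Col10a1 was at 11.33 ± 0.63 (SD, n = 2) in reserve and 16.10 ± 1.18 in hypertrophic arrays, 27.2-fold lower (adjusted p = 0.0233). Higher in reserve arrays were Nnt (62.1-fold, adjusted p = 0.00665), Ucma (50.8-fold, adjusted p = 0.00665), Pdzrn3 (49.2-fold, adjusted p = 0.0162), the peptidyl-prolyl isomerase Fkbp9 (46.5-fold, adjusted p = 0.0162) and the RNA-binding protein Zcrb1 (18.7-fold, adjusted p = 0.0405). Of these 5 only Ucma averaged above the other-organ level in hypertrophic arrays, by less than its SD there, so all 5 folds rest on dim values. The cartilage matrix list was higher by 1.915 (SE 0.355, 21 of 24 genes, adjusted p = 1.14e-08), with 9 genes higher when adjusted over the list alone, against 1, among them Fmod (5.60) and Prelp (4.76), both below the other-organ level in hypertrophic arrays. With an estimated correlation the call was lost (adjusted p = 0.651).

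The osteoclast (1.60, 10 of 10 genes, adjusted p = 0.00999), erythroid (1.42, 8 of 10, adjusted p = 0.0202), resting chondrocyte (1.20, 13 of 17, adjusted p = 0.0214) and ER stress and secretion lists (0.92, 16 of 20, adjusted p = 0.0374) were also higher in reserve than in hypertrophic arrays. In the same order 1, 1, 3 and 4 genes were higher when adjusted over the list alone, against 0 for each over all probe sets, among them the acid phosphatase Acp5 (4.45), the transferrin receptor Tfrc (2.95), Wif1 (4.04) and the collagen chaperone Serpinh1 (5.80). Of these only Tfrc was above the other-organ level in hypertrophic arrays, and Wif1 was below it in both zones. The adjusted p with an estimated correlation was 0.651 for the osteoclast and ER lists and 0.654 for the erythroid and resting lists.

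Only the cartilage matrix call between reserve and hypertrophic arrays held with each array left out, with a difference from 1.226 to 2.607. Without the 46-day hypertrophic array the erythroid difference was 0.37 (adjusted p = 0.677), the osteoclast 1.20 (adjusted p = 0.153) and the ER list's 0.79 (adjusted p = 0.0608). The erythroid call was also lost without the 46-day reserve array (adjusted p = 0.244) and the osteoclast call without the 42-day reserve array (adjusted p = 0.0685). The resting and ER calls were lost without the 42-day hypertrophic (adjusted p = 0.127 and 0.0931), the 42-day proliferative (adjusted p = 0.117 and 0.0605) or the 42-day reserve array (adjusted p = 0.179 and 0.159). The ER call was also lost without the 46-day proliferative array (adjusted p = 0.0514).

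With limma, 6 probe sets were higher and 1 lower in reserve than in hypertrophic arrays, and 36 and 2 with the age block, which held all 7. All 6 named genes lost the call without the 42-day perichondral (adjusted p from 0.0624 to 0.136), the 46-day perichondral (0.0562 to 0.152) or the 42-day reserve array (0.394 to 1). Without the 46-day hypertrophic array Ucma (0.0679), Pdzrn3 (0.0839) and Zcrb1 (0.137) lost it, and without the 46-day reserve array Nnt (0.0961), Pdzrn3 (0.0571), Fkbp9 (0.0635), Zcrb1 (0.167) and Col10a1 (0.246). Pdzrn3, Fkbp9, Zcrb1 and Col10a1 lost it without the 42-day proliferative (0.0541, 0.0501, 0.0687 and 0.0501) or the 46-day proliferative array (0.0721, 0.0721, 0.075 and 0.075). Col10a1 also lost it on values as deposited (-4.61, adjusted p = 0.0984). With median-centred arrays Col10a1 (0.211), Ucma, Pdzrn3 and Fkbp9 (0.0542 for each) and Zcrb1 (0.0889) lost it. The count was 0 without either perichondral array or the 42-day reserve array, 2 without either proliferative array, 3 without the 46-day reserve array and 167 without the 42-day hypertrophic array. It was 0 in a fit to the 4 arrays of these zones alone and 1 with median-centred arrays.

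Proliferative arrays were lower than hypertrophic arrays in both metalloproteinases named by the rule. Mmp9 was at 5.59 ± 0.16 (SD, n = 2) against 12.14 ± 0.48, 93.6-fold lower (adjusted p = 0.025). Mmp13 was at 8.61 ± 0.06 against 14.41 ± 0.45, 55.8-fold lower (adjusted p = 0.00411). Both were below the other-organ level in proliferative arrays. Col10a1 was at 11.78 ± 1.19 against 16.10 ± 1.18, which missed the threshold (adjusted p = 0.0766) and passed it with the age block (adjusted p = 0.00121). The cartilage matrix list was higher in proliferative arrays by 1.45 (SE 0.26, 21 of 24 genes, adjusted p = 2.19e-08), with 4 genes higher when adjusted over the list alone, against 0, among them Ucma (4.27) and Col9a1 (3.235). An estimated correlation ended the call (adjusted p = 0.651). The Gapdh 3' to 5' ratio also parted these zones, at 7.10 and 5.39 in proliferative against 4.30 and 3.63 in hypertrophic arrays at 42 and 46 days. Camera was also run on the lists of these zones with the log2 of this ratio as a covariate, but that outcome was not kept. Single genes were not tested with it.

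Hypertrophic chondrocyte genes (-1.345, 11 of 20 genes lower, adjusted p = 0.00117), matrix proteases (-0.815, 19 of 26, adjusted p = 0.00999), leukocyte and marrow genes (-0.91, 18 of 22, adjusted p = 0.0267) and osteoclast genes (-1.17, 7 of 10, adjusted p = 0.0374) were lower in proliferative than in hypertrophic arrays. Over the list alone, 5 hypertrophic genes were lower, against 2 over all probe sets, among them Ibsp (-5.83), and 1 leukocyte gene, against 0, S100a9 (-3.77), both below the other-organ level in proliferative arrays. The adjusted p with an estimated correlation was 0.696 for the leukocyte list and 0.651 for the other 3.

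Only the cartilage matrix call between proliferative and hypertrophic arrays held with each array left out. Without the 42-day hypertrophic array the leukocyte difference turned to 0.04 (adjusted p = 0.882), and the hypertrophic (-0.90, adjusted p = 0.109), osteoclast (-0.75, adjusted p = 0.387) and protease calls (-0.61, adjusted p = 0.125) were lost. The osteoclast and leukocyte calls were also lost without the 42-day proliferative array (adjusted p = 0.256 and 0.472) or the 42-day reserve array (adjusted p = 0.0868 and 0.0817). The osteoclast call was lost too without the 46-day proliferative (adjusted p = 0.0929) or the 46-day reserve array (adjusted p = 0.0556). The hypertrophic chondrocyte list without its shared members was at -0.77 here (adjusted p = 0.171) and at -0.51 in perichondral minus hypertrophic arrays (adjusted p = 0.185).

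With limma, 1 probe set was higher and 3 were lower in proliferative than in hypertrophic arrays, and 5 and 6 with the age block, which held all 4. Mmp9 lost the call without the 42-day (adjusted p = 0.264) or 46-day proliferative (0.18), either hypertrophic (0.084 and 0.083) or either reserve array (0.138 and 0.107), and Mmp13 without either proliferative array (0.145 and 0.115). Both lost it with median-centred arrays (0.153 and 0.142). The count was 0 without the 42-day proliferative array or with median-centred arrays, 1 without the 46-day proliferative or either reserve array, 2 without either perichondral array, 9 without the 42-day hypertrophic array and 12 without the 46-day hypertrophic array.

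**Figure D2:**
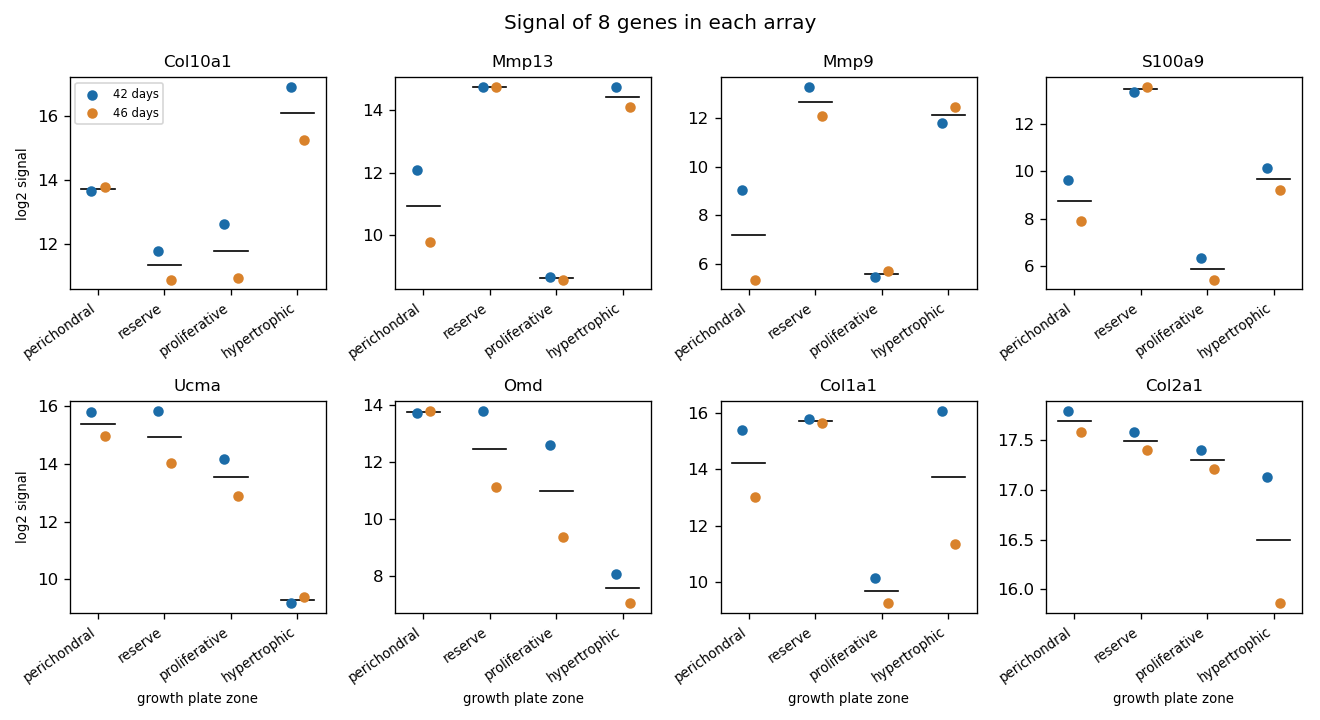
Log2 signal (vertical axis) of 8 genes in each array, by zone (horizontal axis), with 42-day arrays in blue, 46-day arrays in orange and a black line at the mean of both. Col10a1 was at 16.93 and 15.26 in the hypertrophic arrays, and Mmp13 averaged 14.74 in the reserve and 8.61 in the proliferative arrays.

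For enrichment in one zone over each of the other 3, the count was 0 in every zone with limma, and with the age block 1 in the reserve zone, S100a9. Both arrays of a zone lay above the other 6 arrays for 838 probe sets in perichondral, 1315 in reserve, 1369 in proliferative and 1450 in hypertrophic arrays, where chance gives 3.57% of 31042. Pairwise counts at an unadjusted p under 0.05 were 1916 for perichondral and 2515 for reserve against hypertrophic, 2372 for reserve against proliferative and 1714 for proliferative against hypertrophic arrays. Without a variance trend 0 probe sets passed in each of these 4 comparisons, and among probe sets brighter than the median 2, 2, 3 and 0 passed, in the same order.

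Of the 29 lists, 13 were called in at least 1 comparison and 16 in none. Among other cell types, the smallest adjusted p was 0.543 for smooth muscle and pericytes, 0.209 for skeletal muscle, 0.809 for adipocytes and 0.439 for peripheral nerve and glia. It was 0.106 for mitosis, 0.315 for DNA replication, 0.638 for hedgehog and PTHrP signalling, 0.299 for BMP and TGF-beta, 0.802 for FGF, 0.809 for IGF and growth hormone and 0.744 for Notch signalling. It was 0.277 for hypoxia and glycolysis, 0.774 for immediate early and stress genes, 0.199 for oxidative phosphorylation, 0.0656 for ribosomal proteins and 0.106 for genes of other organs.

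Between 46 and 42 days no gene passed the threshold, and 2663 probe sets were higher (8.58%) and 2398 lower (7.73%) at 46 days in 4 of 4 zones, where chance would give 6.25% each if the zones were independent. The genes named here were chosen after their values were seen, for a small p and the same sign in 4 of 4 zones. Mgp, an inhibitor of calcification, averaged 13.04 at 42 and 10.31 at 46 days (-2.72, SE 0.42), Fmod 11.70 and 9.49 (-2.215, SE 0.37) and the glycolytic enzyme Pgk1 13.14 and 11.12 (-2.025, SE 0.33), each with an adjusted p of 0.0693. LOC102548331 averaged 10.11 and 12.07 (1.96, SE 0.359, adjusted p = 0.0823). With limma 0 probe sets passed, while 2616 had an unadjusted p under 0.05 where chance gives 1552. Values as deposited gave 2 higher and 43 lower, median-centred arrays 3 and 137, and leaving out either reserve array 1 and 4. Without the 46-day proliferative and hypertrophic arrays, an alternative added after seeing the data, 38 were higher and 101 lower. The median deposited intensity was higher at 46 days in every zone. The 3' to 5' signal ratio of the Gapdh control was lower, at 3.96 against 8.15 in reserve, 5.39 against 7.10 in proliferative, 3.78 against 4.47 in perichondral and 3.63 against 4.30 in hypertrophic arrays. Age cannot be told apart from any other difference between the pools of each age.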

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

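The tests in this part were all chosen after the results were seen. List standard errors in this part are over genes, which are not independent replicates, and do not measure the spread between pools. For 6 results the difference between zones had opposite signs at 42 and 46 days, which was not tested, since each zone has 1 array per age. In perichondral minus reserve arrays, Acan was at -1.383 at 42 days and 0.054 at 46 days, a gap of 1.436. Pth1r was at -0.83 and 0.752, a gap of 1.582, and Ihh at -0.435 and 0.264, a gap of 0.699. The median of the hypertrophic chondrocyte list in perichondral minus hypertrophic arrays was -1.301 and 0.141, a gap of 1.442. In proliferative minus hypertrophic arrays the osteoclast list's median was -1.982 and 0.081, a gap of 2.063, and the leukocyte list's -2.033 and 0.667, a gap of 2.7. Calls with the same sign at both ages could also differ in size. In reserve minus hypertrophic arrays the resting chondrocyte median was 2.5 at 42 and 0.275 at 46 days, and the erythroid median 0.122 and 2.183. Others were close, such as the osteoclast median in perichondral minus reserve arrays (-1.519 and -1.671).

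Marrow, blood and osteoclast genes were higher in reserve than in perichondral arrays. An array-wide offset is argued against on the values as deposited: the 42 genes of the erythroid, leukocyte and osteoclast lists shifted by a median of 2.066 at 42 and 1.858 at 46 days, above the highest of 100 sets of genes of the same level (0.679 and 0.558). Whether RNA quality is the whole cause was not settled. At 46 days the Gapdh ratio was 3.78 in the perichondral and 3.96 in the reserve array. The list medians there still differed by 2.018 (erythroid), 1.691 (leukocyte) and 1.671 (osteoclast), with 1 array per zone. A fit with the log2 ratio as a covariate cannot decide, since its slope rests on differences between ages within zones. The ratio was lower at 46 days in every zone, so it cannot be parted from age. With this covariate the list medians were 1.63 (SE 0.619) for erythroid, 2.079 (SE 0.395) for leukocyte and 1.735 (SE 0.632) for osteoclast genes. They had been 1.626, 1.773 and 1.644 without it, while other genes moved by a median of 0.366. Camera still called each list with the preset correlation (highest adjusted p = 0.000909). In the fit without the covariate, camera with an estimated correlation lost all 3 calls (adjusted p = 0.651 for each), and it was not run with the covariate. Bone marrow, blood or bone collected with the reserve zone cannot be told apart from expression by reserve chondrocytes, because each RNA holds every cell type of its zone. The bone list, outside this pattern, shifted by 0.444 (SE 0.639) at the age with the smaller median, and the cartilage matrix list by -0.109 (SE 0.128), and neither sets a bound. The abundant marrow genes S100a8 and S100a9 averaged 13.58 and 13.45 in the reserve arrays.

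Bone and marrow genes were higher in the 42-day than in the 46-day hypertrophic array, with Col1a1 at 16.09 against 11.33. Col10a1 was highest in the hypertrophic array at each age, by at least 1.485 with a residual SD of 0.715. This lead is between single arrays and bears only on a full swap with another zone. A hypertrophic array that holds part of another zone could still lead, so it cannot be told apart. Across the brightest share of 0.2 of probe sets, the 46-day hypertrophic array correlated at 0.735 with the 46-day proliferative array. Its correlation with the 42-day hypertrophic array was 0.531. Bone or marrow next to the hypertrophic zone, collected at 42 days, cannot be told apart from an age change in this zone. The endothelial list, outside this pattern, differed by -0.337 (SE 0.451). Its medians of 7.93 at 42 and 7.99 at 46 days lay below the other-organ level, so it cannot decide between them. An age change acting alike in every zone, as the whole cause, is argued against for the erythroid list only. Its medians in the other 3 zones averaged -0.069 (SD 0.232) against 2.017 in hypertrophic arrays. The averages were -0.186 (SD 0.684) against 1.792 for leukocyte and -0.214 (SD 0.31) against 0.9 for bone genes. An SD over 3 zones is too loose to set a bound at such gaps, so for these lists it cannot be told apart. Nor can it for osteoclast genes, at 0.671 (SD 0.817) against 0.599. An age change in this zone alone stays open, as untested. The zone was picked for its gap, and each zone gives 1 difference between single arrays. A pool difference in 1 hypertrophic array therefore cannot be told apart either.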

How the results depend on the processing

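Counts follow the order perichondral against reserve, proliferative and hypertrophic, reserve against proliferative and hypertrophic, then proliferative against hypertrophic, where the reported counts were 0, 0, 9, 7, 7 and 4. The cause of each change was not tested unless given. With age as a replicate block they were 3, 13, 55, 60, 38 and 11, with 1 reserve-enriched probe set. Without a variance trend the last 4 were all 0. Keeping probe sets above the other-organ level in a zone, or those brighter than the median, left 2, 3, 2 and 0 in the last 4. Median-centred arrays gave 1, 1 and 0 in the comparisons with hypertrophic arrays and 140 for age. Values as deposited gave 14 for reserve against proliferative and 45 for age. An adjusted p under 0.01 left 2, 4, 2 and 1 in the last 4, by construction. Reserve against proliferative moved to 11 with robust variance, 25 with array weights, 16 with a pseudocount of 64 (5 for age) and 27 with only the 4 arrays compared. That fit gave 9 for perichondral against reserve, 0 for reserve against hypertrophic and 1 for the last comparison. The last comparison also gave 2 with array weights or a pseudocount of 1, and 1 with 1 probe set per gene.

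Leaving out each array gave 0 to 1, 0 to 5, 0 to 50, 0 to 45, 0 to 167 and 0 to 12, with 0 to 1 reserve-enriched and 0 to 5 for age; the lone array of a zone is assumed to vary like the others. Without the 46-day proliferative and hypertrophic arrays, an alternative added after seeing the data, the counts were 1 for perichondral against reserve, 5 for perichondral against hypertrophic, 30 for reserve against proliferative and 139 for age. Of 18 named gene differences past the threshold this left 6 (Nnt in both its comparisons, S100a9, Mmp13 and Steap4 in reserve against proliferative, Col10a1 in reserve against hypertrophic arrays) and ended 12. Of 33 list calls it left 28, ending the resting and fibrous calls of perichondral against hypertrophic and the osteoclast, erythroid and ER calls of reserve against hypertrophic arrays.

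Of 33 list calls, 0 held with camera's estimated correlation and 0 with fry, 32 with the age block and 29 with the mean over all probe sets of a gene. That mean ended the protease call of perichondral against reserve, the Wnt call of perichondral against hypertrophic, and the osteoclast and leukocyte calls of proliferative against hypertrophic arrays. Of 18 named gene differences past the threshold, 0 reversed under the alternatives run. All 18 were lost without a variance trend, while 6 held with either filter on dim probe sets, 7 with median-centred arrays, 10 with only the 4 arrays compared and 18 with the age block. With an array left out the fewest held without the 42-day reserve or the 42-day perichondral array, 5 each. Perichondral minus reserve, Ihh turned to 0.035 as deposited. With each array left out, Ihh ran from -0.485 to 0.318, Pth1r from -0.447 to 0.356 and Acan from -1.71 to 0.372, and the leukocyte list in proliferative minus hypertrophic arrays from -1.819 to 0.042. Dim genes limit all of this: their folds rest on levels below the other-organ level.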

Other observations

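The differences of the mitosis list within each age and the other splits of the arrays were tests chosen after the results were seen. Mki67, a marker of dividing cells, lay between 12.22 and 14.02 in all 8 arrays. As a hypothesis, the proliferative zone may hold more mitotic RNA than each other zone. This cannot be told apart here: in proliferative minus hypertrophic arrays the 21 genes of the mitosis list differed by -0.243 (SE 0.266) at 42 days and -0.186 (SE 0.336) at 46 days. Proliferative minus reserve was at -0.056 (SE 0.352) at 42 days and -1.229 (SE 0.292) at 46 days, so that gap rests on the 46-day arrays. Proliferative minus perichondral was at -0.248 (SE 0.316) at 42 days and -0.123 (SE 0.22) at 46 days. All 6 mean differences were below 0, the opposite of what this hypothesis needs, but 5 of them by less than 2 standard errors. These errors are over genes of single arrays, which are not independent replicates, so they do not measure the spread between pools. Camera called no comparison of this list (smallest adjusted p = 0.106).

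For age, other splits of the arrays cannot test the count past the threshold, because the real split gave 0 with limma and each of the 32 splits that could be fitted beside zone must give at least as many. The highest other gave 115, and it parts the proliferative and hypertrophic arrays by age and keeps the arrays of each other zone together. What sets these arrays apart was not tested. At an unadjusted p under 0.05 the real split gave 2616 probe sets and the highest other 3022. Of the 8 splits that part every zone pair, too few for a share under 0.05, the highest other gave 1744.

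The 0.99 quantile of the deposited intensity was lower at 46 than at 42 days in every zone, and lowest in the 46-day proliferative (4983.2) and 46-day hypertrophic (5817.8) arrays. The ratio of 3' to 5' control signal for Gapdh ran from 3.63 to 8.15 over the 8 arrays and was lower at 46 days in every zone.

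The probe set with the largest difference between reserve and proliferative arrays past the threshold (10.77, adjusted p = 0.039 with limma) is annotated to several genes and so has no gene name here. It was at 14.70 and 16.25 in the reserve arrays, 14.70 and 5.64 in the hypertrophic arrays, 9.55 and 8.78 in the perichondral arrays and 4.85 and 4.56 in the proliferative arrays, at 42 and 46 days. The proliferative values are below the other-organ level, so the size of this difference rests on dim values.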
